A study of Mus musculus with 6 samples.

How the data were processed

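RNA was measured by ribosomal-RNA-depleted total RNA sequencing in fresh mouse splenocytes, in 3 wild-type (WT) and 3 Top3b-knockout (Top3b-KO) libraries. The deposited table holds expected counts per gene symbol for the 6 libraries. Reads were aligned with STAR to the mouse build mm39, per the submitters' processing notes. The counting tool, its strand setting, the annotation release and the treatment of reads with several matches are not given in the sources used here. The sample description gives a read length of 150 bases and the protocol gives 101. The protocol also describes a pair of library kits and sequencers, so which preparation each library had is not settled. The R-loop CUT&Tag assay that the design text names was not analysed here.

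The table had 56413 symbols, of which 22655 had no count in any library. Values that were not whole within a tolerance of 1e-06 occurred for 72 symbols, 33 of them tested, and all values were rounded to whole numbers first. All 6 count columns were used. Total counts ranged from 9941019 to 25473405 per library. A floor of 3 counts corresponds to between 0.118 and 0.302 CPM (depth-scaled counts), and such floors cover counting error only.

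Genes were kept by edgeR's filterByExpr, which left 18716. The main test was edgeR's quasi-likelihood F test with TMM factors, robust dispersion and genotype as its only term, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. CPM values are scaled by the TMM factors, and errors on them are standard deviations over 3 libraries. The labels call the libraries replicates and do not say whether they came from separate animals, so every p-value measures the spread between these libraries. Single measures were compared by two-sided exact permutation tests, which with 3 against 3 cannot give a p under 0.1.

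Gene lists for splenic cell types, immune responses, DNA and RNA metabolism and control tissues, 44 in all, were fixed before the data were examined, as were the tests, the rule for named genes and most of the other settings tried. One of them, of sex-linked genes, served only as a label check. Those with at least 5 tested members, 40 lists, were compared by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 40 lists, and again with an estimated correlation and by fry. The marginal zone macrophage, neuronal and pancreas lists had too few tested members. A list score is the mean log2 CPM of its members in a library.

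Named genes were Top3b, the genes past the threshold (up to 12 per direction, with groups that did not overlap and a mean of at least 1 CPM), and the 5 with the smallest p-value in a direction where fewer than 5 passed. For each list described, up to 4 members that passed were named, or otherwise the 2 most abundant, and genes within 5 Mb of Top3b that passed. Predicted-gene symbols were excluded, and 2 genes that the rule names are not reported here. Any other gene in the text was chosen after its values were seen.

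The test was tested on simulated counts for the 18716 genes with the means and library sizes of these libraries. Over all runs 250 changes of each size were planted, all in genes with a mean of at least 1 CPM. For Top3b-KO against WT, over 5 runs, it recovered 9.60% of 1.2-fold changes, 59.2% of 1.5-fold, 84.4% of 2-fold and 99.2% of 4-fold, with 52 false among 683 calls. A T cell list shifted by 0.3 on the log2 scale was recovered, and 0 of the other lists were called. Genes were simulated independently of each other, whereas the estimated correlation in the real data was 0.25 for the T cell list and 0.34 for the histone list. The simulation therefore says nothing about false list calls where members vary together.

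Gene lengths, GC content, transcript classes and sequence came from GENCODE M21, to which 49306 symbols (87.4%) matched, and neighbours of Top3b from RefSeq on GRCm38. That build differs from mm39, so no positions are printed. The class of a gene is that of its longest transcript. Alternatives changed the scaling, filter, test, threshold, replicate block, list test and libraries included. Corrections for length and GC, thinning to the smallest total, and leaving out symbols with fractional values were added after the data were seen.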

Results

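Total RNA of mouse splenocytes was sequenced to compare the transcriptomes of WT and Top3b-KO animals. Top3b encodes topoisomerase III-beta, and the study's stated interest is its part in immune dysregulation and tumour formation. The WT libraries held 15448261, 15262063 and 15860288 counts, and the Top3b-KO libraries 24510381, 25473405 and 9941019 (exact permutation p = 0.4). Xist had between 18652 and 47930 counts in every library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had between 0 and 3 counts each, so all 6 libraries had the pattern of female cells. The first principal component held 30.7% of the variance and the second 22.5%, and neither separated the genotypes. Top3b-KO replicate 3 stood farthest out on the first component, at 34.6, and was also the library with the fewest counts. Correlations of log2 CPM between libraries ranged from 0.991 to 0.996.

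Top3b itself, on chromosome 16, was lower in the knockout. Its counts were 1472, 1326 and 1449 in the WT libraries and 1257, 1216 and 491 in the Top3b-KO libraries. Scaled for depth, this was 91.0 ± 4.06 CPM in WT and 49.8 ± 1.66 CPM in Top3b-KO (SD, n = 3), a log2 fold change of -0.87 (SE 0.071) and a ratio of 0.547. The adjusted p was 5.78e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Top3b was lower in 3 of 3 knockout libraries, and the remaining counts cannot be assigned to exons inside or outside the deleted part from a count per gene. The counts alone therefore do not show that Top3b was lost in full in these libraries.

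Clec16a was the single other gene past the threshold. It rose from 49.5 ± 2.27 CPM in WT to 69.5 ± 3.05 CPM in Top3b-KO (SD, n = 3), a log2 fold change of 0.49 (SE 0.074), higher in 3 of 3 knockout libraries, with an adjusted p of 0.028 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Leaving out any one of 5 libraries (all but WT replicate 3) moved that adjusted p to between 0.058 and 0.30. The antisense gene Gm15558 was taken to overlap Clec16a, which the GENCODE M21 sequences used here do not show. Gm15558 was at 1.27 ± 0.639 CPM in WT and 2.95 ± 0.511 CPM in Top3b-KO. Where the pair overlap, their reads cannot be told apart without a stated strand setting.

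**Figure D1:**
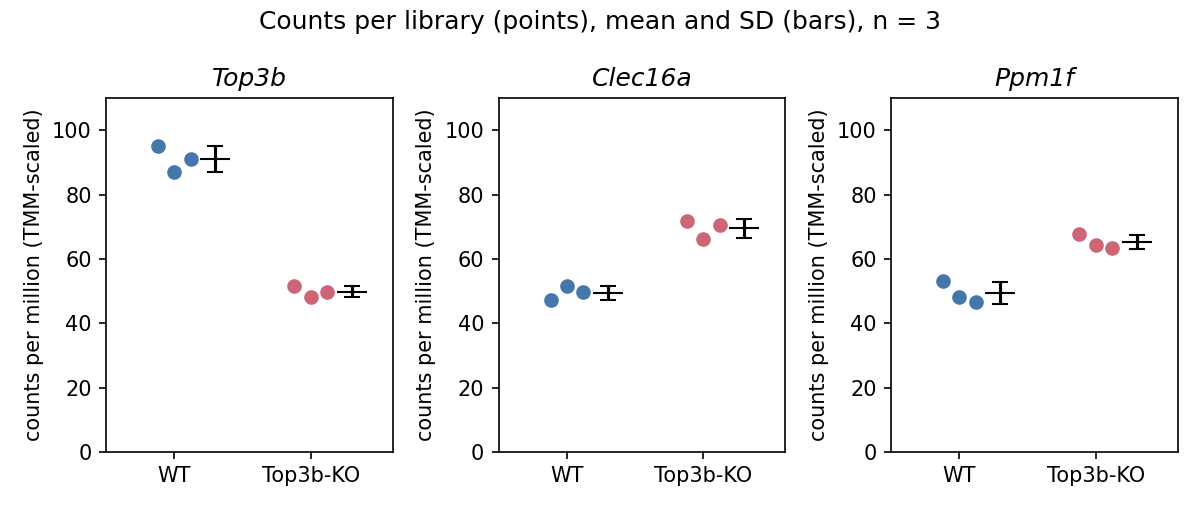
TMM-scaled CPM of Top3b, Clec16a and Ppm1f in each library (points), with the mean and SD of 3 libraries per genotype (bars). For each gene the genotypes do not overlap, with means of 91.0 and 49.8 for Top3b, 49.5 and 69.5 for Clec16a, and 49.4 and 65.1 for Ppm1f.

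The next genes by p-value did not pass this test. Ppm1f, a neighbour of Top3b, was at 49.4 ± 3.47 CPM in WT and 65.1 ± 2.21 CPM in Top3b-KO, with a log2 fold change of 0.40 (SE 0.076) and an adjusted p of 0.20 by edgeR's test with Benjamini-Hochberg adjustment. Ighv14-4 (log2 fold change 0.69), Ighv1-19 (0.65) and Ptgs2 (0.62) had adjusted p of 0.35, 0.35 and 0.53 by the same edgeR test. On the lower side, mt-Co2 was at 6.46 ± 0.782 CPM in WT and 3.07 ± 0.337 CPM in Top3b-KO, a log2 fold change of -1.05 (SE 0.173) with an adjusted p of 0.061 by edgeR. Nearly all of the mt-Co2 sequence also occurs in nuclear copies, so its counts are uncertain. The 7SL gene Rn7s2 (-0.85), mt-Atp6 (-1.23) and the histone gene H4c4 (-0.42) had adjusted p of 0.49, 0.53 and 0.53 by edgeR. Of 114 tested genes within 5 Mb of Top3b, 1 passed, which was Top3b.

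Across all 18716 tested genes, 1 gene was higher and 1 lower at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 1033 genes (5.52%, against 5% expected with no difference), 342 higher and 691 lower in Top3b-KO. The 3 libraries of one genotype lay above the 3 of the other for 2062 genes (11.0%, against 10% by chance). Of 9798 genes at 10 CPM or more, 9772 (99.7%) lay within 1.5-fold between genotypes. In simulated data of this design the test recovered 59.2% of 1.5-fold and 9.60% of 1.2-fold changes, so changes of the smaller size were mostly not detectable. Those runs held many planted changes and gave 683 calls over 5 runs, which makes the adjusted threshold easier to reach. With 2 calls in the real data, recovery is likely lower than these shares.

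**Figure D2:**
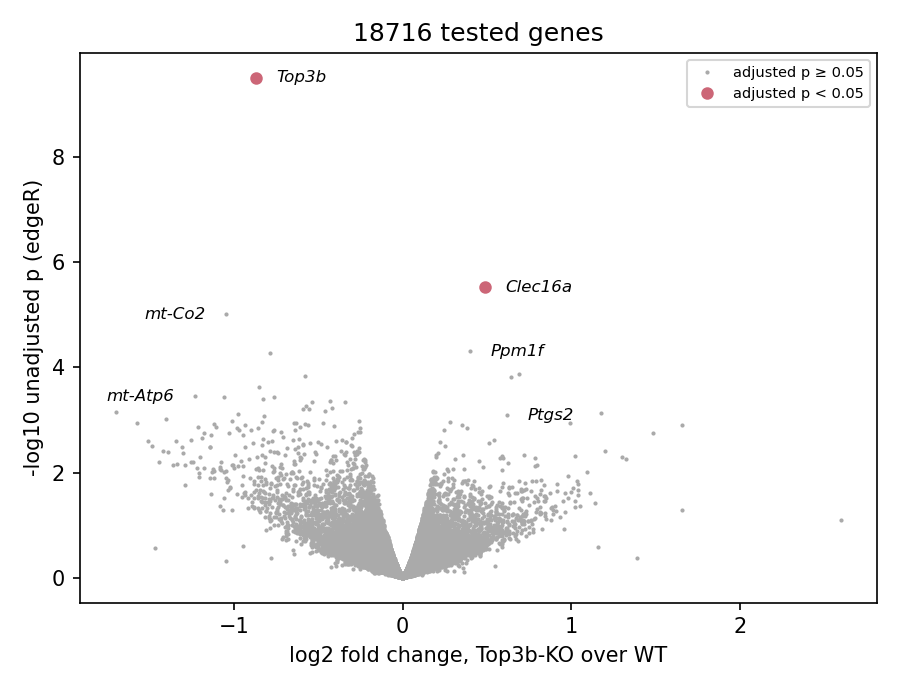
Log2 fold change of Top3b-KO over WT (x axis) and -log10 of the unadjusted edgeR p (y axis) for the 18716 tested genes. Top3b at -0.87 and Clec16a at 0.49 are the points with an adjusted p under 0.05.

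The immune groups relevant to the study's question had small median log2 fold changes. For the type I interferon response list, 32 tested genes, the median log2 fold change was -0.015 and camera's adjusted p was 0.81. Its most abundant members, Ifi209 and Parp14, had log2 fold changes of 0.094 and 0.075. Nucleic acid sensing genes had a median of -0.043, with Samhd1 at 0.066 and Unc93b1 at -0.14. Inflammatory cytokine and NF-kB genes had a median of -0.0044, with Nfkb1 at -0.016, and Ptgs2 was the member that passed when adjusted over the list alone. In each of the 40 lists, 0 members passed over all genes by edgeR's adjusted p, and the counts at an unadjusted p under 0.05 ran from 0 to 29 per list. Adjustment over a list alone was not corrected for the number of lists, so some members would pass it by chance.

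By camera with the preset correlation, 7 of 40 lists passed an adjusted p of 0.05, 1 higher and 6 lower. With an estimated correlation 0 lists passed (1 at an unadjusted p under 0.05, lowest adjusted p 0.80), and by fry 0 (2 at an unadjusted p under 0.05). None of the following calls held under either of these. Camera run on the edgeR statistics, again with the preset correlation, gave 9 lists, all 7 among them. The further lists were the cell cycle (adjusted p 0.030 by that test) and immunoglobulin constant region lists (0.031), both lower. Replication-dependent histone genes were lower, with a median log2 fold change of -0.27 over 53 members, 49 of them below 0, and an adjusted p of 1.01e-13 (adjusted p = 0.85 with an estimated correlation). Adjusted over the list alone, 7 histone genes passed edgeR's test, which were H2bc3, H3c1, H3c11, H3c3, H3c4, H3c7 and H4c4. The abundant H1f2 went from 404 ± 92.4 to 319 ± 25.9 CPM and H1f4 from 180 ± 40.6 to 142 ± 21.7 CPM. Histone list scores were 3.68, 3.60 and 3.41 in WT and 3.44, 3.31 and 3.05 in Top3b-KO, with an exact permutation p of 0.2 and overlapping genotypes. Histone genes form multigene families, and how reads shared within a family were counted is not given in the sources used here.

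Cytosolic ribosomal protein genes had a median of -0.066 over 86 members and camera's preset adjusted p was 9.73e-06 (adjusted p = 0.85 with an estimated correlation). Rpl4 and Rps3, the most abundant members, had log2 fold changes of -0.032 and -0.042. Erythroid genes had a median of -0.30 (preset adjusted p 3.80e-04 by camera, adjusted p = 0.85 with an estimated correlation). Among its members, Hbb-bs was at 831 ± 245 CPM in WT and 636 ± 104 CPM in Top3b-KO, and Slc25a37 had a log2 fold change of -0.044. Red pulp macrophage genes had a median of -0.11 (preset adjusted p 0.0051 by camera, adjusted p = 0.85 with an estimated correlation), with Slc40a1 at -0.11 and Vcam1 at -0.0076. Myeloid progenitor granule genes had a median of -0.38 (preset adjusted p 0.0088 by camera, adjusted p = 0.85 with an estimated correlation). Elane, at 2.54 CPM in WT and 1.31 CPM in Top3b-KO, passed when adjusted over the list alone (0.56 over all genes, edgeR's adjusted p). Mpo had a log2 fold change of -0.39 and Hdc of 0.23. Plasmacytoid dendritic cell genes had a median of -0.14 (preset adjusted p 0.035 by camera, adjusted p = 0.80 with an estimated correlation). Ly6d passed when adjusted over the list alone, and Spib and Tcf4 had log2 fold changes of -0.18 and -0.051. T cell genes had a median of 0.059 (preset adjusted p 0.0051 by camera, adjusted p = 0.85 with an estimated correlation), with Tcf7 at 0.10 and Lck at 0.057.

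Leaving out 1 library moved the medians of all these lists except the histone list by over 1.5 times. The erythroid median was -0.098 without WT replicate 2, -0.50 without Top3b-KO replicate 1, -0.20 without Top3b-KO replicate 2 and -0.18 without Top3b-KO replicate 3. The ribosomal protein median was -0.042 without WT replicate 2, -0.10 without WT replicate 3 or Top3b-KO replicate 2, and -0.026 without Top3b-KO replicate 1. For red pulp macrophage genes it was -0.16 without Top3b-KO replicate 1 and -0.065 without Top3b-KO replicate 3. For myeloid progenitor granule genes it was -0.25 without WT replicate 2 and -0.12 without Top3b-KO replicate 2. The plasmacytoid dendritic cell median was -0.043 without Top3b-KO replicate 3. The T cell median was 0.12 without WT replicate 1 and changed sign, to -0.013, without WT replicate 3.

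The other 33 lists had preset adjusted p between 0.058 and 0.91 by camera. Among B-lineage lists the median log2 fold changes were -0.054 for B cell genes, -0.047 for marginal zone, -0.028 for germinal centre, -0.090 for age-associated and -0.074 for plasma cell genes. Pax5 had a log2 fold change of -0.018. Immunoglobulin constant region genes had a median of -0.14, and Iglc2, which lies within 5 Mb of Top3b, passed when adjusted over the list alone. Immunoglobulin variable region genes had a median of 0.049 over 176 members, of which 29 had an unadjusted p under 0.05, and Ighv1-19 and Ighv14-4 passed when adjusted over the list alone. The lambda light chain locus neighbours Top3b, and the lambda share of light chain constant region counts was 25.1 ± 3.89% in WT and 23.2 ± 2.02% in Top3b-KO (exact permutation p = 0.6, n = 3).

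Further lymphoid and myeloid lists had medians of 0.0079 for CD4 and follicular helper T cells, 0.045 for regulatory T cells, -0.11 for cytotoxic CD8 T cells, -0.048 for exhaustion and checkpoint genes and -0.069 for natural killer cells. The medians were 0.023 for neutrophils, -0.014 for monocytes, -0.084 for conventional dendritic cells, 0.16 for basophils and mast cells, -0.075 for megakaryocytes and platelets, -0.20 for stem and progenitor cells and -0.064 for stromal and endothelial cells. The neutrophil genes Ltf and Ngp varied more within genotypes than between them. Ltf was at 237 ± 88.6 CPM in WT and 260 ± 204 CPM in Top3b-KO, with 495 CPM in Top3b-KO replicate 3. MHC class II genes had a median of -0.042 and MHC class I genes of -0.048.

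Lists of nucleic acid metabolism also had small median log2 fold changes, while single members ranged more widely, down to -0.90 among p53 targets. R-loop resolution genes had a median of 0.063 (preset adjusted p 0.058 by camera, adjusted p = 0.80 with an estimated correlation), with Ddx5 at 0.097. Their list score was higher in 3 of 3 knockout libraries, at the smallest exact permutation p of 0.1. List scores of that kind, without overlap between genotypes, occurred for 2 of 40 lists, where chance gives 4. Topoisomerases and partners had a median of 0.029, with Top1 at 0.047 and Top2b at 0.063. The medians were 0.048 for DNA damage response and repair, 0.0044 for p53 targets, -0.094 for the cell cycle, -0.032 for oncogenes and lymphoma-associated genes, -0.022 for immediate early and heat shock genes, 0.030 for the unfolded protein response and 0.041 for mitochondrially encoded genes. The sign of the median or mean differed from that of camera's test for 6 lists. These were the exhaustion and checkpoint, neutrophil, inflammatory cytokine, DNA damage, p53 and mitochondrially encoded lists. The mitochondrially encoded list had a mean log2 fold change of -0.17 and a score difference of -0.16. Its members mt-Atp6 and mt-Co2 were lower and passed when adjusted over the list alone.

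**Figure D3:**
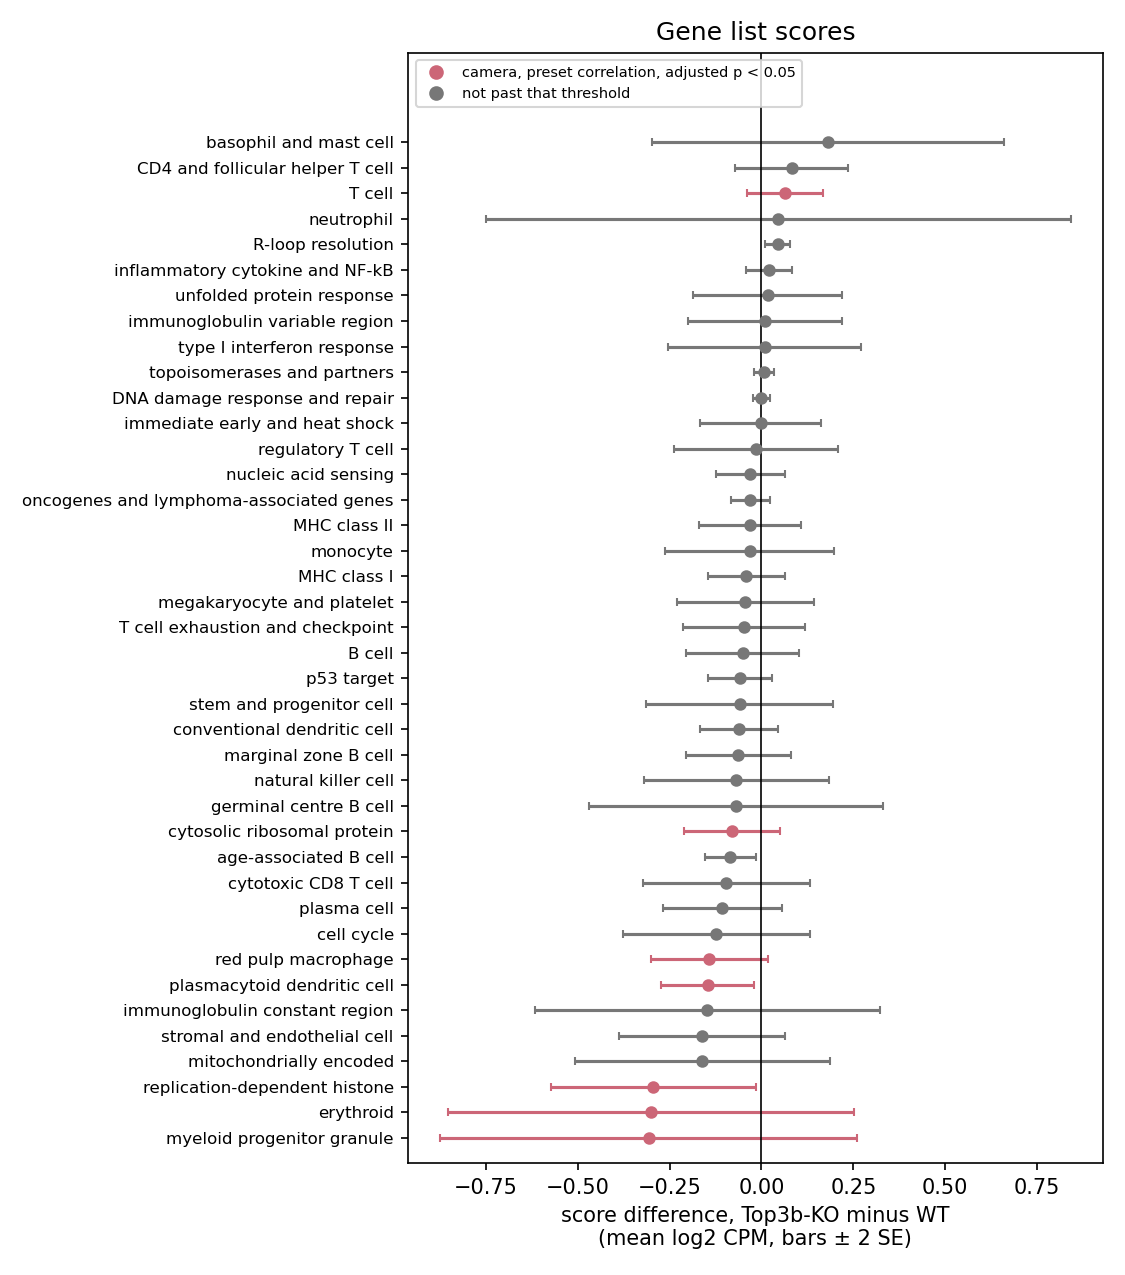
Difference in list score (mean log2 CPM of the members) between Top3b-KO and WT for the 40 tested lists, with bars of 2 standard errors from 3 libraries per genotype. Lists in colour passed camera with the preset correlation, and 0 of the 40 passed with an estimated correlation. The histone list lies at -0.29 and the neutrophil list, at 0.046, has the widest bar.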

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

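The length, GC and thinning corrections, and the test without symbols of fractional values, were chosen after the data were seen. Top3b was lower and past the threshold under all 19 alternatives (log2 fold change -0.92 to -0.84). Beside 2 genes in the main test, 44 passed with no filter on low counts, 7 with DESeq2, 4 with the GC trend removed, and 1 each with robust=FALSE, limma-voom, voomWithQualityWeights and glmTreat against a 1.2-fold change. Both main genes were among those of the first 3. With an absolute log2 fold change of at least 1 also required, 0 passed. With no fold requirement, 1033 had an unadjusted p under 0.05 by edgeR and 649 by DESeq2. Leaving out a library gave 1 to 32 genes, with 32 without WT replicate 3, 9 without Top3b-KO replicate 1, 2 without Top3b-KO replicate 3 and 1 without each of the others. Other scalings, the stricter filter, the length correction, thinning and leaving out fractional symbols gave 2. The replicate block gave 41 genes, both main ones included, and 9 lists. Among the 41 were the histone genes H1f5, H4c4, H3c7, H3c3, H4c12, H3c1, H4c8, H2bc3, H3c11 and H1f4, all lower. The 7SL genes Rn7s1, Rn7s2 and Rn7s6 and the red pulp macrophage gene Hmox1 (log2 fold change -0.56) were also lower and among them. Deviations of same-numbered libraries correlated at 0.156, -0.0067 and 0.0093. The first was the highest of all WT and Top3b-KO pairs, but not every library correlated best with its own number. So few libraries cannot settle whether the numbers pair them, so the replicate block stays an alternative. Clec16a stayed higher in all 19 (0.45 to 0.53) and missed the threshold in 7. These were robust=FALSE (adjusted p 0.071), limma-voom (0.082) and leaving out each of 5 libraries, within a range of 6.67e-06 to 0.30 over all alternatives. Ppm1f and Rn7s2 passed in 4 of 19 alternatives and mt-Co2 in 5, including DESeq2 (adjusted p 0.028, 0.0051 and 0.030). H4c4, Ighv1-19, Ighv14-4 and Ptgs2 passed in 3 each and mt-Atp6 in 2. All 8 of these genes passed with no filter and with the replicate block. Beside 7 lists, 0 passed camera with an estimated correlation, 0 passed fry, and 11 passed with the GC trend removed. Camera on the edgeR statistics with the preset correlation gave 9. Leaving out a library gave 9 to 15 lists, with 15 without WT replicate 1 and 12 without each of Top3b-KO replicates 1 and 3. The T cell list without WT replicate 3 had a median of -0.013 (adjusted p 0.30), and the erythroid list without WT replicate 2 had an adjusted p of 0.34. The ribosomal protein list missed the threshold without Top3b-KO replicate 1 (0.11) and with the length trend removed (0.055), and so did the myeloid progenitor list under the stricter filter (median 0.015), without WT replicate 2 (0.23) and without Top3b-KO replicate 2 (0.15). The plasmacytoid list did so with no filter (0.054) and without WT replicates 2 (0.095) or 3 (0.072) or Top3b-KO replicate 3 (0.13), and the red pulp macrophage list without WT replicate 1 (0.10) or Top3b-KO replicate 3 (0.085), by camera. The robust setting does not enter the list test. The cause of these changes was not tested. Depth limits mainly Top3b-KO replicate 3, where 3 counts equal 0.302 CPM.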

Other observations

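The tests of cycling cells, of flanking DNA, of cell type shares and of the mitochondrial total were chosen after the result was seen. So were the length, GC and depth corrections as alternatives. The look at pseudogenes, miscellaneous RNA, the lambda locus, immunoglobulin variable genes and T cell receptor genes was chosen then too. Histone genes, the chromosome 16 pair Clec16a and Ppm1f, and the mitochondrial genes mt-Co2 and mt-Atp6 were the patterns weighed.

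Replication-dependent histone genes had a median log2 fold change of -0.27 and a score lower by -0.29 (SE 0.140) in Top3b-KO. The median was -0.22 with the trend on transcript length removed, -0.17 with the GC trend removed and -0.28 after thinning to the smallest total. With the preset correlation, camera's adjusted p stayed at 1.94e-11, 9.61e-09 and 1.51e-14, but without any correction the list had adjusted p = 0.85 with an estimated correlation and 0.92 by fry, so the difference itself is not established. Removing the length trend took -0.037 (SE 0.0085) of the score difference away, which argues against a smooth trend on length as the main cause. The trend was fitted over all genes with a span of 0.5, so a bias confined to the shortest transcripts stays open. Thinning took -0.025 (SE 0.0098) away. It does not decide on depth, because scores are already scaled for depth and thinning could move them little. Removing the GC trend took away -0.083 (SE 0.048), and 2 standard errors reach -0.18, so GC content stays open as a large part of the difference. These taken-away parts were computed after the medians were seen. The cell cycle score was lower by -0.12 (SE 0.127), and the histone difference exceeded it by a further -0.17 (SE 0.070). That gap was over 2 standard errors, the criterion set for this test, but it rests on 3 libraries per genotype. It also takes both scores to fall equally when fewer cells cycle, which was not tested. The gap therefore does not decide whether fewer cycling cells are the whole cause of the histone difference. A partial contribution stays open too, since the error of the cell cycle score is as large as the score difference. Of the 32 cell cycle members, 25 were lower and 7 higher, with a median log2 fold change of -0.094. Mki67 and Pcna, the most abundant, had log2 fold changes of -0.021 and 0.12. The 10 tested genes of the miscellaneous RNA class, 7SL among them, had a median of -0.76, with 6 lower at an unadjusted p under 0.05, among them Rn7s1 (-0.98), Rn7s2 (-0.85) and Rn7s6 (-1.19), while Rn7sk was at -0.11. Small nucleolar and small nuclear RNA genes had medians of 0.059 and -0.038. Whether WT and Top3b-KO libraries were prepared together is not given in the sources used here, so a difference in preparation stays open and untested. The loss of Top3b stays open and untested beyond the genotype comparison.

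Clec16a and Ppm1f, ranked 2 and 4 by p-value among all genes, lie on the chromosome of Top3b, about 6.2 Mb and 0.03 Mb away in GRCm38. DNA of another strain kept around the targeted locus could alter such genes. Top3b, Clec16a, Ppm1f and the antisense Gm15558 were left out of the test of this. Of 164 other tested genes within 10 Mb, 7.32% had an unadjusted p under 0.05, against 5.71% of 15339 genes elsewhere (Fisher's exact test p = 0.39, 95% exact interval 3.84 to 12.4%). The low-p neighbours include 4 of 8 lambda light chain genes, Iglc1 (-0.22), Iglc2 (-0.27), Iglv1 (-0.22) and Iglv2 (-0.45), a single B cell locus. Without that locus the share was 5.13% of 156 genes (Fisher's exact test p = 1), computed after the first share was seen. The interval includes both the background share and an excess, so this explanation stays open. The test took a shift in cell type shares to raise a list by at least 0.40, the change of Ppm1f. Cd8a counts toward both the cytotoxic CD8 T cell and conventional dendritic cell lists, so a score can mix cell types. A score may therefore move less than a share. Cell types without a tested list, such as marginal zone macrophages, were not covered. The highest rise among 21 cell type lists was 0.18 for basophils and mast cells (SE 0.239), and the intervals of that list and the neutrophil list reached past 0.40, so this test did not decide. A second look, added because that test was undecided, found 0 of the 21 lists with a score higher in every knockout library than in every WT library, as both genes were. The same limits apply to the second look, so it does not decide either. An effect of the targeted allele on its neighbour Ppm1f was not tested.

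mt-Co2 and mt-Atp6 were lower in Top3b-KO by -1.05 and -1.23 on the log2 scale without passing edgeR's adjusted threshold in the main test. mt-Co2 passed in 5 of 19 alternatives (adjusted p 0.030 by DESeq2) and mt-Atp6 in 2, one of them edgeR with no filter on low counts (adjusted p 2.72e-04). Of their 100-base stretches, 99.5% in mt-Co2 and 99.48% in mt-Atp6 occur in a nuclear copy annotated in GENCODE M21, against a median of 3.20% for the other mitochondrial protein genes. Both genes had few counts, mt-Co2 at 6.46 CPM in WT beside 3465 CPM for mt-Co1. mt-Co3, with 99.8% shared stretches, had a log2 fold change of -0.52 and its nuclear copy Gm28437 one of -0.30. The other genes sharing over 90% of stretches, mt-Nd4l and mt-Nd3, had too few counts to be tested. mt-Nd4l was at 1.05 ± 0.478 CPM in WT and 0.449 ± 0.145 CPM in Top3b-KO, and mt-Nd3 had 1 to 4 counts per library. mt-Nd4, with 60.8% shared, was at 257 CPM in WT with a log2 fold change of -0.011. The nuclear copy Gm10925 of mt-Atp6 was at -0.61, and the copies of mt-Co2, Gm13341 and Gm28661, were at -0.74 and -0.65. A drop in mitochondrial transcripts as a whole was argued against, because the median of the 11 other mitochondrial genes was 0.061. The SE of their mean, 0.056, is taken over genes and not libraries, and genes of this list vary together (estimated correlation 0.49). Mitochondrially encoded genes held 1.00 ± 0.194% of counts in WT and 1.03 ± 0.0767% in Top3b-KO (SD, n = 3, exact permutation p = 0.8). The low counts of mt-Co2 and mt-Atp6 may be the few reads left after matches shared with nuclear copies. How the counting treated such reads is not given in the sources used here. Shared sequence would lower the counts in both genotypes, so by itself it does not account for the fall in Top3b-KO. The copies Gm10925, Gm13341 and Gm28661 were lower too, so the values do not show reads moving to these copies.

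Processed pseudogenes, another class that shares sequence with its parents, leaned the same way. Of 911 tested, 150 had an unadjusted p under 0.05, 142 of them lower in Top3b-KO, which was 16.5% against 4.96% of other genes. Their mean log2 CPM was 0.76, 0.85 and 0.64 in WT and 0.53, 0.59 and 0.60 in Top3b-KO. The highest count among other splits of the 6 libraries was 100, but 1 other split had a larger median difference, 0.154 in size against 0.145 for the real one. Immunoglobulin variable genes had 29 of 176 members with an unadjusted p under 0.05 (18 higher and 11 lower), 16.5% against 5.42% of other genes. Other splits gave between 12 and 35. Of 52 T cell receptor J genes, 9 had an unadjusted p under 0.05 by edgeR, all higher (17.3%, median log2 fold change 0.26). For T cell receptor V genes it was 2 of 57, both higher (3.51%, median 0.12). Other splits were not counted for the T cell receptor classes.

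Splitting the 6 libraries into 3 and 3 in all 10 ways gave as many genes as the genotypes did in 3 splits, the real one included, with 2 genes for the real split and 27 for the highest other. That split set WT replicates 1 and 2 with Top3b-KO replicate 1 against the rest, and its count, several times the real one, points to a structure among the libraries that genotype does not describe. For camera with the preset correlation, 9 of the 10 splits gave as many lists, with 7 for the real split and 22 for the highest other. With an estimated correlation each split gave 0 lists, where the real split had 1 at an unadjusted p under 0.05. The histone median was 0.27 in size for the real split and 0.33 for the same split that gave 27 genes. The 10 splits are too few for a share under 0.05.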
